A study of Allium sativum with 42 samples.

How the data were processed

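RNA-seq libraries of garlic tissues were analysed from a single deposited table. The submitters' processing notes name Bowtie2, a short-read aligner, and RSEM, which assigns reads to transcripts and estimates their abundance. Versions of both, the reference sequence and the gene annotation are not given in the sources used here. Per the labels' protocols, total RNA was extracted from each sample with a plant RNA kit, cDNA libraries were made from each extract, and they were sequenced as read pairs on an Illumina HiSeq instrument. The values deposited by the authors are FPKM, fragments per kilobase of transcript and per M (mega) mapped fragments, for 58219 gene IDs in 42 columns. Column names equalled sample titles, every column was given to 1 sample by that name, and 0 columns were left over. The unit was taken from the values: FPKM sums ranged from 1.11 to 1.30 M per library. FPKM is scaled to the mapped fragments of a library, so a steep rise of a few genes lowers the values of all others, although FPKM sums are not fixed. How reads that fit several near-identical genes were counted is not known.

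Read counts were recovered because each gene's FPKM values in the deposited table were whole multiples of 1 step per gene and library. All 45750 genes above 0 gave whole numbers within a tolerance of 0.001 counts, among them 100% of the 38950 genes above 0 in at least 10 libraries. For genes above 0 in very few libraries this says little, since a single value is always a whole multiple of itself. On simulated counts of 4691 genes, each above 0 in at least 10 simulated libraries, the procedure returned 99.7% of the single counts exactly. Recovered totals, used here as depth, ranged from 5.9 to 35.4 M per library. They served for depth, for counts of reads behind a low value, for thinning and for 1 alternative fit, and not for the main tests, since the deposited unit is FPKM. Estimates by RSEM need not be whole, so how the authors counted reads remains open. No pair of replicates agreed within sampling noise: the lowest chi-square per degree of freedom was 11.61.

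Groups were taken from the tissue and age in the labels, and replicate numbers from the titles (1, 4 and 7 for buds, 1 to 3 elsewhere). Where the labels and the growth protocol gave different days for the tissue samples, the labels were used and bulbs labelled 217 days were tried in place of those labelled 212 days. The series text also names 48 sequenced samples where 42 are listed, and the 42 were used.

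Tests were run on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a fit of group means, a variance trend on mean expression and Benjamini-Hochberg adjustment. Genes with at least 1 FPKM in at least 3 libraries of a fit were tested, which left 30430 genes in the fit of 24 bulb libraries and 33536 in the fit of 21 libraries of 7 tissues. A call needed an adjusted p below 0.05 and a log2 difference of at least 1. Differences on this scale understate changes of genes near 1 FPKM. A gene elevated in a tissue had to pass against each of the 6 others. Bulbs were compared at 227 against 192 days, between consecutive ages, along a linear term for age and by a moderated F test over the 8 ages. Tissue-elevated lists were tested in bulbs with camera, 2-sided, with a preset inter-gene correlation of 0.01 and with an estimated one, adjusted over the 7 lists. Correlations across bulb libraries used 100000 permutations in Python 3 with NumPy.

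Genes named in the text followed a rule fixed before the data were examined. Since IDs are not paired with names in the table, it took the 2 largest rises and falls among genes called at 227 against 192 days, with a mean of at least 10 FPKM in the higher group and no overlap between the libraries, and the 2 elevated genes per tissue with the largest difference from the nearest tissue and a mean of at least 10 FPKM. Lists of genes by function that had been drawn up by keyword could not be applied for the same reason. The 20 abundant, steeply rising genes and Asa3G02941.1 were chosen after their values were seen.

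The tests were tried on simulated data with 100 genes changed by 1.5 and 100 changed by 3 on the log2 scale. Among 30052 genes, the test of 227 against 192 days found 73% and 96% of them with 8 calls among unchanged genes, that of 227 against 222 days 71% and 96% with 5, the trend 84% and 100% with 2, and the F test 62% and 96% with 12. Among 31677 genes, the tissue test found 53% and 96% with 0 calls among unchanged genes. The simulated values were normal noise around a common mean per gene, with a spread pooled over the groups. Few genes were changed, they were drawn from genes detected in more libraries than the filter asks, and no library stood apart. The rates therefore check the procedure and do not give the power of the tests on the real libraries.

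Alternatives fixed beforehand were a pseudocount of 0.1, no filter beyond a value above 0, a filter of 5 FPKM, median-of-ratios scaling, rescaling to TPM, quantile normalization, the replicate number as a block, fits of only the libraries compared, 217-day in place of 212-day bulbs, an estimated correlation, and leaving out each library in turn. For the correlations with age they were TPM, the top 10 genes and a minimum of 5 FPKM. Alternatives chosen after seeing the data were voom on the recovered counts, tissue fits without buds or without flowers, scaling without the 20 abundant genes, and thinning to the lowest bulb total, 12.8 M.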

Results

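Transcript levels were measured by RNA-seq in garlic (Allium sativum), cultivar Ershuizao, a bulb crop propagated from cloves. The set held 42 libraries in 14 groups of 3. Bulbs were taken at 8 ages, every 5 days from 192 to 227 days, a span that per the labels ran from before the start of bulb expansion to its end. The other 6 groups were buds labelled 10 days, flowers labelled 217 days, and leaves, pseudostems (the false stem made of rolled leaf bases), garlic sprouts and roots labelled 212 days. The labels and the growth protocol differed for the last 4: the protocol dates the harvest of the tissues to the day that falls on the 217-day bulb sampling. The deposited table gave FPKM for 58219 gene IDs, of which 12469 were at 0 in every library. Whole read counts recovered from the FPKM values summed to between 5.9 M (leaf replicate 1) and 35.4 M (replicate 2 of the 197-day bulbs). Mean depth was 30.2 M ± 0.66 (SD, n = 3) in 192-day bulbs, 22.0 M ± 4.36 in 227-day bulbs and 10.6 M ± 4.85 in leaves, so low transcripts were counted less precisely in leaves. The table gives no gene names, so genes are identified by ID alone. Nothing in the labels says that replicates came from separate plants, and p-values therefore measure only the spread between these samples, which may be technical.

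Bulbs of neighbouring ages and the other tissues formed an ordered set of profiles. The mean profile of buds was nearest to that of 192-day bulbs (r = 0.928 across genes, which are not independent replicates), and leaves and pseudostems were nearest to each other (r = 0.923). The flower profile was nearest to those of bulbs at 217 and 222 days (both r = 0.916) and 227 days (r = 0.915), and lay further from 192-day bulbs (r = 0.784). Along the bulb series the correlation with the 192-day mean fell from 0.983 at 197 days to 0.85 at 227 days, with 1 step out of order: it was 0.935 at 202 days and 0.951 at 207 days. Within groups the lowest correlation between replicates was 0.938 or higher (root 0.938), except in 227-day bulbs. There the lowest pair, which included replicate 2, correlated at 0.86, while replicates 1 and 3 correlated at 0.972.

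**Figure D1:**
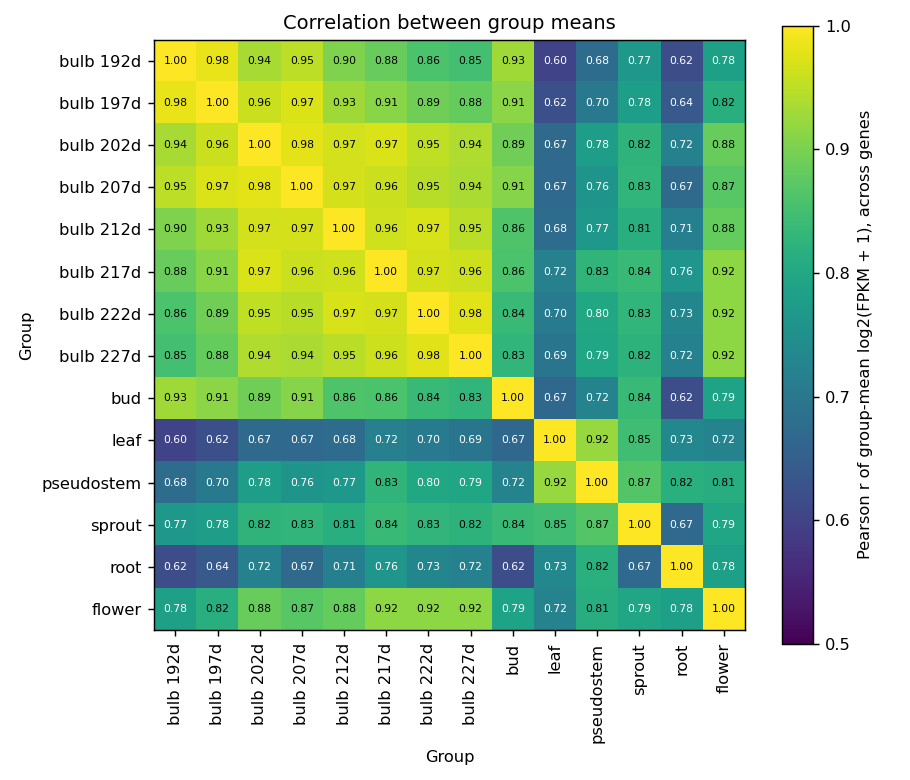
Pearson correlation between the mean log2(FPKM + 1) profiles of the 14 groups, across genes, with the value written in each cell. Flower sits closest to the 3 oldest bulb groups, bud to the 2 youngest, and leaf to pseudostem.

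Replicate 2 of the 227-day bulbs also differed in which genes were detected. In it, 146 genes lay under 0.5 FPKM that had at least 5 FPKM in each of the 41 other libraries, and 116 of these had no read at all. A further 205 genes had at least 5 FPKM in this library and under 0.5 FPKM in each of the other 41. No other library lacked a gene in this way, and no other library had more than 2 genes to itself. This library was kept in all comparisons, and the numbers of genes higher and lower at 227 than at 192 days are given also without it.

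**Figure D2:**
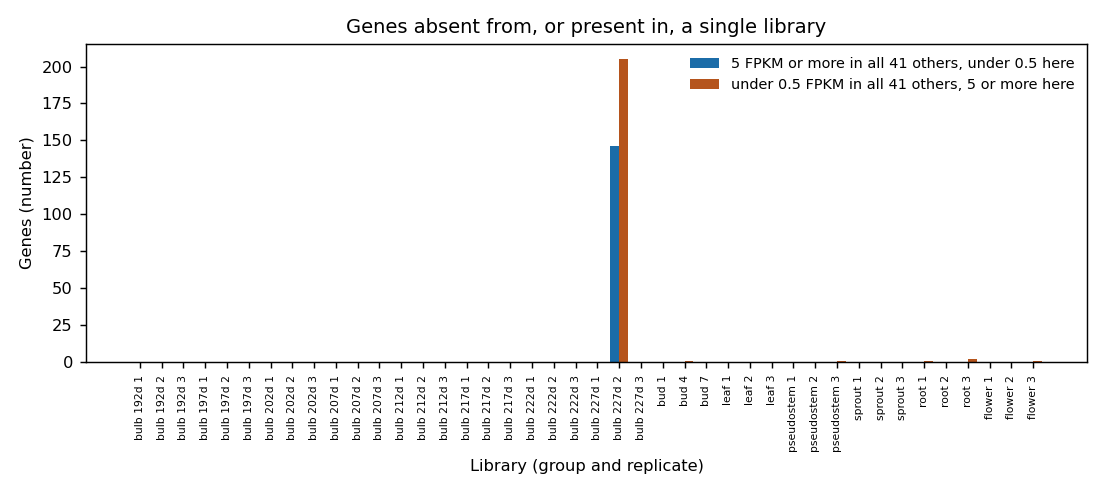
Number of genes per library that were absent from that library but at 5 FPKM or more in all 41 others, and of genes at 5 FPKM or more in that library but under 0.5 FPKM in all others. Replicate 2 of the 227-day bulbs had 146 and 205 such genes, and every other library had 0 of the first kind and at most 2 of the second.

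The first comparison asked how bulbs at the end of the series differed from bulbs at its start. Asa5G05839.1 showed the largest rise by the fixed rule, from 2.69 ± 2.66 FPKM at 192 days to 67300 ± 1300 FPKM at 227 days (SD, n = 3), a log2 difference of 14.39 ± 0.49 (SE, limma, adjusted p = 6.32e-13) on the log2(FPKM + 1) scale. Asa0G00303.1 rose from 2.06 ± 1.52 to 34900 ± 21300 FPKM (log2 difference 13.30 ± 0.66). The large SD of the latter came from replicate 2, at 10400 FPKM against 47600 FPKM in the highest library. In flower the 2 genes averaged 49700 ± 9760 and 34500 ± 4170 FPKM, and they were low in root (0.0981 and 0.0971 FPKM) and leaf (1.17 and 0 FPKM). The largest falls were those of Asa6G02702.1, from 220 ± 13.0 to 0.827 ± 0.747 FPKM (log2 difference -6.99 ± 0.58, adjusted p = 1.85e-08), and Asa2G02745.1, from 311 ± 45.2 to 1.70 ± 0.911 FPKM (log2 difference -6.90 ± 0.61). Both falling genes were also abundant in buds, at 131 ± 39.8 and 201 ± 35.2 FPKM, and had at most 2 reads in any leaf, pseudostem or sprout library.

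Of 30430 genes tested, 2531 were higher and 6417 lower at 227 than at 192 days (limma, adjusted p below 0.05 and at least 1 on the log2 scale). The largest changes were rises: 82 genes rose and 47 fell by at least 5 on the log2 scale, and 12 rose and 0 fell by at least 8. The balance of the calls depended on scaling. With FPKM as deposited 28.3% of the called genes were higher, and the median of all genes was -0.28. Median-of-ratios scaling moved that median by 0.29 and gave 3985 higher and 4169 lower genes (48.9% higher), and quantile normalization moved it by 0.23 and gave 3629 and 4304 (45.7% higher). Scaling without 20 abundant, steeply rising genes, chosen after the data were seen, turned the balance to 5074 higher and 3267 lower genes (60.8% higher). Without replicate 2 of the 227-day bulbs, 3049 genes were higher and 5419 lower, of which 2101 and 5091 were also called with it.

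A small number of genes came to hold a large part of the transcript pool. The 20 genes that rose by at least 5 on the log2 scale and reached a mean of at least 1000 FPKM at 227 days, a rule set after the values were seen, held 0.0451% ± 0.0113 of summed FPKM at 192 days (SD, n = 3). Their share was 0.245% ± 0.030 at 197 days, 2.33% ± 0.556 at 202 days, 2.99% ± 1.70 at 207 days, 8.99% ± 1.12 at 212 days, 9.96% ± 7.96 at 217 days, 30.5% ± 4.68 at 222 days and 34.4% ± 6.33 at 227 days. The wide spread at 217 days came from replicate 3, at 19.2%, against 5.34% and 5.39% in the others. At 227 days replicate 2 was the highest, at 41.7%. Flowers held 25.2% ± 3.62 in the same 20 genes, while buds, leaves, pseudostems, sprouts and roots held from 0.028% to 0.296% on average. Of the 20 genes, 17 were called higher in flower than in each of those 5 tissues, and 13 had means under 1 FPKM in both leaf and root. Without sequences it was not known which of the 20 are near-identical copies, so the division of reads among them is uncertain.

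**Figure D3:**
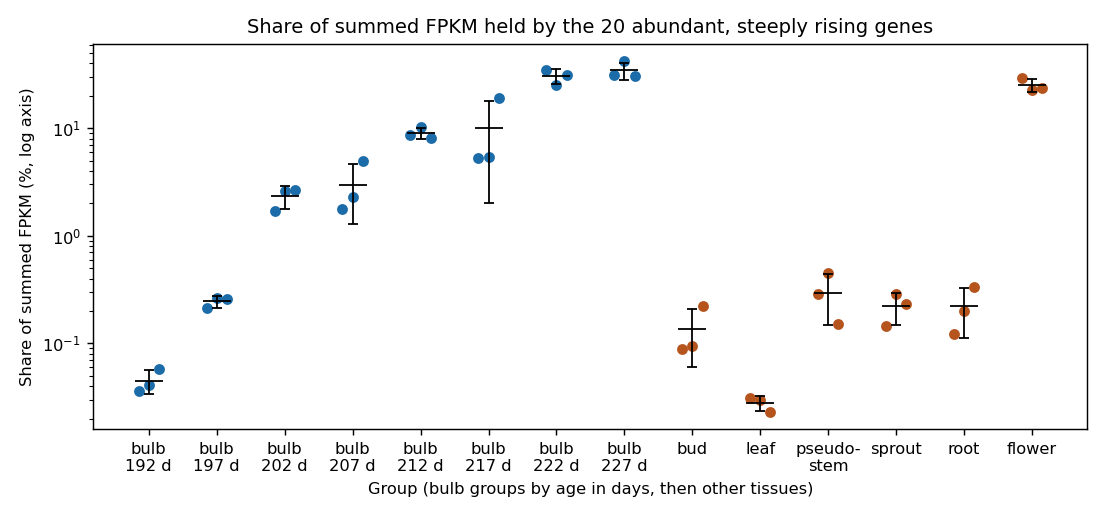
Share of summed FPKM (percent, log axis) held by the 20 abundant, steeply rising genes in each library (points), with the group mean (bar) and SD (whiskers, n = 3), bulbs in blue and other tissues in orange. The bulb means climb from 0.0451% to 34.4%, the flower mean reaches 25.2%, and the means of the other tissues stay under 0.3%.

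The concentration of the transcriptome rose with bulb age, while no linear or monotone relation of the number of detected genes with age was detectable. The 100 most abundant genes of each library held 18.7% ± 0.16 of summed FPKM at 192 days and 47.8% ± 5.98 at 227 days. The rise was uneven. The share was 20.4% ± 0.47 at 197 days, 20.1% ± 0.48 at 202 days and 20.7% ± 2.0 at 207 days. It was then 25.9% ± 1.15 at 212 days, 26.0% ± 7.36 at 217 days and 44.4% ± 4.03 at 222 days. Over the 24 bulb libraries this share correlated with age (Pearson r = 0.84, Spearman rho = 0.90, 2-sided permutation p = 1e-05 for both, the smallest that 100000 resamples can give, adjusted p = 2e-05 over 2 relations). It held at r = 0.83 without replicate 1 of the 192-day and of the 227-day bulbs, chosen among the 6 libraries that tied as farthest from the median age. Libraries were shuffled singly, so the permutation tests count the 3 libraries of an age as independent. Where these are not separate plants, the p-values are too small. Genes with at least 1 FPKM numbered 26391 ± 122 at 192 days and 25808 ± 1345 at 227 days, with 25386 ± 230 at 197 days, 26983 ± 266 at 202 days, 26980 ± 230 at 212 days and 26353 ± 119 at 222 days (SD, n = 3). A rise and fall of this kind was not tested, and the number did not correlate detectably with age (r = 0.03, permutation p = 0.90, and rho = 0.11, p = 0.63; adjusted p = 0.90 and 0.63). Without the same 2 libraries r was 0.01. The lowest number, 24255, was that of replicate 2 of the 227-day bulbs.

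Changes between consecutive samplings were uneven. The step from 197 to 202 days gave the most calls, with 1361 genes higher and 765 lower. The step from 192 to 197 days gave 123 and 171, that from 207 to 212 days 401 and 296, that from 212 to 217 days 631 and 514, and that from 217 to 222 days 320 and 870. Between 202 and 207 days 9 genes were higher and 2 lower. Between 222 and 227 days limma called 1 gene, Asa3G02941.1, which is named because it was the only one: it went from 0.259 ± 0.203 to 2.73 ± 1.17 FPKM, against 3119 genes at an unadjusted p below 0.05. These step counts rested on few libraries. When each of the 24 bulb libraries was left out in turn, they ranged from 93 to 395 for the first step, from 959 to 2741 for the second, from 0 to 193 for the third, from 104 to 2044 for the fourth, from 175 to 1930 for the fifth, from 428 to 1829 for the sixth and from 0 to 7 for the last. Between 192 and 197 days the count was 93 and 116 without replicates 1 and 2 at 192 days, and 118 and 186 without replicates 1 and 2 at 197 days. Between 197 and 202 days it was 1323 and 1161 without replicates 2 and 3 at 197 days and 959 without replicate 2 at 202 days. Between 202 and 207 days it was 193 without replicate 3 at 207 days, 45 without replicate 2 at 227 days, 22 and 20 without replicates 2 and 1 at 217 days, 7 and 2 without replicates 2 and 3 at 222 days, 5 and 2 without replicates 1 and 3 at 227 days, 12 without replicate 3 at 217 days, and 0 without any 1 of the other libraries. Between 207 and 212 days it was 2044 without replicate 3 at 207 days, 1131 without replicate 2 at 227 days, 169 and 104 without replicates 1 and 2 at 207 days, and 176 and 124 without replicates 1 and 2 at 212 days. Between 212 and 217 days it was 1930 and 263 without replicates 1 and 2 at 217 days, and 175 and 243 without replicates 1 and 2 at 212 days. Between 217 and 222 days it was 1829 and 428 without replicates 2 and 3 at 222 days. In the last step it was 0 without replicate 1 or 2 at 227 days, 7 without replicate 3 at 227 days, and 2 and 4 without replicates 1 and 2 at 222 days. The limma fit of the 6 libraries compared alone called 724 genes between 192 and 197 days, 134 between 207 and 212 days, 13 between 217 and 222 days and 0 between 202 and 207 and between 222 and 227 days. Median-of-ratios scaling gave 749 genes between 217 and 222 days, and quantile normalization gave 793 there and 169 between 192 and 197 days. Between 202 and 207 days both gave 0, as did TPM and voom, against 3197 genes at an unadjusted p below 0.05 in the fit of all bulb libraries.

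With age as a linear term, 2921 genes rose and 5718 fell over the 35 days. Of the genes called between the end points, 2215 of the higher ones also rose with age and 5293 of the lower ones also fell, and 0 went opposite ways. The trend was fitted on libraries that include those of the end points, so opposite calls were unlikely and the overlap is not independent support. Any difference among the 8 ages was called for 13088 genes (43% of those tested). Their highest mean was most often at 192 days (4688 genes), followed by 217 days (2123), 197 days (1499), 212 days (1366), 202 days (1030), 227 days (1004), 222 days (847) and 207 days (531). The order depended on single libraries and on scaling. Without replicate 2 or replicate 3 of the 207-day bulbs 911 and 1231 genes peaked at 207 days, without replicate 2 of the 217-day bulbs 1273 peaked at 217 days, and without replicate 2 of the 222-day bulbs 1357 peaked at 222 days. Under median-of-ratios scaling 2980 peaked at 192 days, 574 at 202, 166 at 207, 1297 at 222 and 2101 at 227 days, and under quantile normalization 578 peaked at 202, 212 at 207 and 1861 at 227 days. The other peak counts stayed within 1.5 times under both.

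The second comparison asked which genes marked each tissue, with 212-day bulbs standing for bulb. A gene counted as elevated where it was called higher than in each of the 6 other tissues. Of 33536 genes tested, 1903 were elevated in bud, 1797 in root, 979 in leaf, 361 in flower, 279 in sprout, 260 in bulb and 218 in pseudostem. The bud count was 1172 with median-of-ratios scaling and 1245 with quantile normalization, both below the root count under the same scaling. The sprout count was 585 without buds. Age and tissue go together for buds and flowers. In root, 353 of the elevated genes stood at least 3 above the nearest tissue on the log2 scale, against 126 in bud, 51 in flower, 27 in leaf, 18 in sprout, 16 in pseudostem and 11 in bulb. The nearest tissue was bulb for 1044 of the bud-elevated genes and 123 of the flower-elevated ones, and sprout for 481 of the leaf-elevated ones. Between pairs of tissues, leaf and pseudostem differed in the fewest genes (5128) and bud and root in the most (16945).

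Among the named genes, those of root and flower stood highest above the nearest of the other 6 tissues, with 212-day bulbs as bulb. Asa3G02364.1 averaged 363 ± 141 FPKM in root and had 0 reads in every bud, leaf, pseudostem, sprout and 212-day bulb library, with at most 1 read in a flower library (log2 difference from the nearest tissue 8.42 ± 0.18). Asa0G00352.1 averaged 239 ± 78.8 FPKM in root (7.44 ± 0.22). In flower, Asa0G05981.1 averaged 189 ± 116 FPKM (7.37 ± 0.27) and Asa4G03684.1 averaged 180 ± 89.4 FPKM (7.35 ± 0.21). The same 2 genes had 8.35 ± 9.45 and 4.35 ± 5.11 FPKM in 222-day bulbs and at most 1 read in any bud, leaf, pseudostem, sprout, root or 212-day bulb library. In bud, Asa6G06118.1 averaged 348 ± 70.6 FPKM (6.11 ± 0.20) and Asa7G04417.1 94.6 ± 4.21 FPKM (6.10 ± 0.15). The former was also seen in young bulbs, at 57.2 ± 8.16 FPKM at 192 days and 0.646 ± 0.146 FPKM at 227 days. Pseudostem was marked by Asa7G05450.1, at 415 ± 385 FPKM with a range from 81.7 to 837, and Asa4G05023.1, at 244 ± 101 FPKM. Their differences from the nearest tissue were 6.28 ± 0.53 and 6.25 ± 0.27. Sprout was marked by Asa1G06391.1, at 187 ± 16.0 FPKM (5.15 ± 0.51), and Asa5G00694.1, at 33.7 ± 24.5 FPKM (4.67 ± 0.30). Leaf was marked by Asa2G00788.1, at 193 ± 38.1 FPKM (4.83 ± 0.30), and Asa8G03350.1, at 78.2 ± 21.4 FPKM (4.56 ± 0.35). Adjusted p-values from limma for these 12 genes were 8.41e-08 or smaller.

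The bulb genes at the top of the list depended on the age taken. Asa3G00052.1 averaged 92.9 ± 14.8 FPKM at 212 days (log2 difference from the nearest tissue 4.06 ± 0.53), with its highest mean, 161 ± 34.9 FPKM, at 202 days and 8.46 ± 5.54 FPKM at 227 days. Asa6G05368.1 averaged 59.5 ± 33.6 FPKM at 212 days (4.02 ± 0.43) and 5.55 FPKM or less on average at every other bulb age. With 217-day bulbs in place of 212-day bulbs, 98 genes were elevated in bulb, and the differences of these genes were 1.65 and -1.02, neither of which was called. Without the flower libraries 461 genes were elevated in bulb, and without buds 1008 were.

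The third comparison asked how the genes that marked each tissue moved in bulbs between 192 and 227 days. Each list was made by comparison with the 212-day bulbs of the same series, so none of the lists is independent of the series. For the bud list this favours a fall, since its genes had to be lower in 212-day bulbs than in bud. The 212-day mean profile was nearer to that of 227-day bulbs (r = 0.949) than to that of 192-day bulbs (r = 0.904). Tests of the bud list do not separate its fall from this selection. Bud-elevated genes fell: of 1784 measured, 1480 fell and 3 rose, with a median log2 difference of -2.01, which is 1.73 below the median of all genes. Flower-elevated genes rose: of 307 measured, 158 rose and 5 fell, with a median of 1.27, which is 1.56 above that of all genes. Along the series the bud list stood at -1.16 at 202 days, -0.96 at 207 days and -1.46 at 212 days, and the flower list at 0.56 at 202 days and 1.13 at 222 days. Against all other genes, by limma's camera test with a preset correlation, the adjusted p was 7.97e-40 for the bud list and 5.85e-30 for the flower list. With an estimated correlation the adjusted p was 0.0482 for the bud list and 0.00018 for the flower list, and without replicate 2 of the 227-day bulbs these were 0.0582 and 0.00117. The 20 abundant genes described above held 25.2% of summed FPKM in flowers and 34.4% in 227-day bulbs. They were chosen for their rise to 227 days, and how many of them are in the flower list was not counted. Their shares are therefore not separate support for the rise of that list.

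Lists from the other tissues held both genes that rose and genes that fell. Genes that did not pass the filter in the bulb fit were left out of them. Tested were 151 of 218 pseudostem-elevated genes, 983 of 1797 root-elevated, 190 of 279 sprout-elevated and 676 of 979 leaf-elevated ones. For comparison, of all 30430 genes 2531 rose and 6417 fell, with a median of -0.28. Set against that median, the list medians were higher by 1.08 for pseudostem, 0.60 for root, 0.49 for sprout, 0.31 for bulb and 0.12 for leaf. Of 151 pseudostem-elevated genes 45 rose and 6 fell (median 0.79), of 983 root-elevated genes 174 rose and 84 fell (median 0.31), and of 190 sprout-elevated genes 45 rose and 23 fell (median 0.21). Of 260 bulb-elevated genes 78 rose and 59 fell (median 0.03). The median of this list was highest at 212 days (1.51), the age at which it was made. Camera with a preset correlation called these 4 lists upward against other genes (adjusted p from 1.29e-11 to 0.000105), and none held with an estimated correlation: the adjusted p was 0.236 for pseudostem, 0.336 for root, 0.133 for sprout and 0.387 for bulb. Of 676 leaf-elevated genes 83 rose and 98 fell, and the list was not called (adjusted p = 0.0884). Its median was -0.16 and its mean -0.06 while the test pointed up, relative to other genes, and the median was 0.12 under median-of-ratios scaling. Without replicate 2 of the 227-day bulbs, 67 pseudostem-elevated and 286 root-elevated genes rose.

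**Figure D4:**
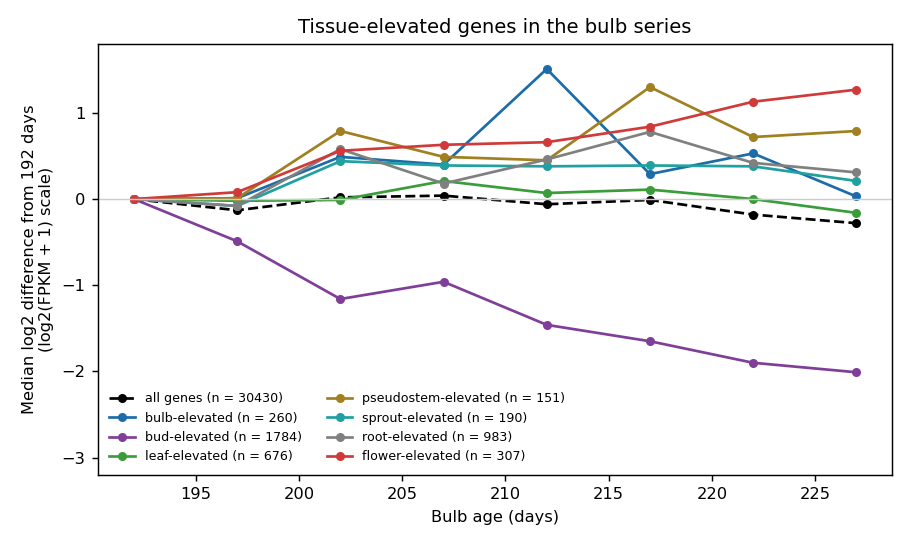
Median log2 difference from 192-day bulbs, on the log2(FPKM + 1) scale, of the genes elevated in each tissue (lines) and of all genes tested (dashed), against bulb age in days. The bud list falls to -2.01, the flower list climbs to 1.27, and the bulb list peaks at 212 days, the age at which it was defined.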

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

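The fits with voom on recovered counts, without buds, without flowers and scaled without the 20 abundant genes, and the thinned counts, were chosen after the data were seen. All other settings were fixed before. Lists were drawn anew where a setting changed the tissue fit. Over settings other than leaving out 1 library, 213 values for gene counts other than by peak age, lists and correlations with age kept their direction and side of the threshold or stayed within 1.5 times. A further 28 counts moved by more, 6 list calls were lost, 1 list was newly called and 1 reversed. Of peak-age counts and named genes, 238 kept theirs, 8 counts moved, 1 call was lost and 1 gene reversed. Both correlations with age kept theirs under every setting, with r from 0.83 to 0.88 for the top 100 genes and from -0.06 to 0.29 for the number of detected genes when each library was left out. Thinning every bulb library to 12.8 M reads gave r = 0.84 and 0.02.

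Scaling moved the balance of calls at 227 against 192 days, to 3985 higher and 4169 lower genes with median-of-ratios scaling and to 5074 and 3267 with libraries scaled without the 20 abundant genes. Median-of-ratios scaling also gave 749 genes between 217 and 222 days, 1172 genes elevated in bud, and a median of 0.16 for the bulb list, which was then not called. Quantile normalization gave 169 genes between 192 and 197 days, 793 between 217 and 222 days and 1245 elevated in bud. The 11 genes between 202 and 207 days became 3 with a pseudocount of 0.1, 4 without a filter, 3 with the replicate block and 0 with median-of-ratios scaling, TPM, quantile normalization, voom or the 6 libraries alone. Fits of the 6 libraries compared gave 724 genes between 192 and 197 days, 134 between 207 and 212 days, 13 between 217 and 222 days and 0 between 222 and 227 days, from fewer samples. The filter of 5 FPKM also gave 0 in the last step, and called the leaf list (median -0.21, test pointing up). With an estimated correlation the lists of bulb (median 0.03), pseudostem (0.79), sprout (0.21) and root (0.31) were not called. Bulbs labelled 217 days gave 98 bulb-elevated genes, and neither Asa3G00052.1 (1.65) nor Asa6G05368.1 (-1.02, reversed) was then called. Without flowers 461 genes were elevated in bulb. Except where a setting's own construction shows it, the cause was not tested.

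Replicate numbers did not pair the samples: deviations from group means of same-numbered libraries had a median correlation of -0.018, against 0.002 for different numbers, and 13.2% of the pairs were above 0.1. With the replicate number as a block, 1008 genes were elevated in bulb and 580 in sprout, the bulb list fell (median -2.13) and the sprout list was not called (median -0.24). The blocked tissue fit had to leave out buds, whose numbers differ, and leaving them out without a block gave 1008 and 585 genes, so the missing buds made the counts change. The block gave no value for buds.

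Leaving out 1 library kept the counts at 227 against 192 days within 2140 to 3049 higher and 5419 to 7448 lower, those along age within 2672 to 3480 and 5252 to 5930, and those among ages within 12230 to 14342. The tissue counts stayed within 194 to 294 for bulb, 1666 to 1923 for bud, 864 to 1113 for leaf, 178 to 243 for pseudostem, 224 to 289 for sprout, 1320 to 1813 for root and 309 to 383 for flower. List medians stayed within -0.08 to 0.13 for bulb, -2.08 to -1.96 for bud, -0.23 to -0.06 for leaf, 0.60 to 1.0 for pseudostem, 0.04 to 0.41 for sprout, 0.13 to 0.57 for root and 1.17 to 1.32 for flower, and the leaf list was called without replicate 2 or replicate 3 of sprout (medians -0.11 and -0.14). Step counts ranged from 93 to 395 for 192 to 197 days, from 959 to 2741 for 197 to 202, from 0 to 193 for 202 to 207, from 104 to 2044 for 207 to 212, from 175 to 1930 for 212 to 217, from 428 to 1829 for 217 to 222 and from 0 to 7 for 222 to 227. Among genes differing over the 8 ages, those peaking at 207 days numbered 911 and 1231 without replicates 2 and 3 of that age, those peaking at 217 days 1273 without its replicate 2, and those peaking at 222 days 1357 without its replicate 2. The shallowest library, leaf replicate 1, had 5.9 M reads, which limits detection of low genes there.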

Other observations

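The tests in this part were chosen after the data were seen, and except for thinning as a test of the balance of calls, only after the result they address was seen.

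Flowers and late bulbs shared abundant transcripts that were far lower in the other tissues. The 20 abundant, steeply rising genes held 25.2% of summed FPKM in flowers, against 30.5% and 34.4% in bulbs at 222 and 227 days and at most 0.296% on average in the other tissues. Genes elevated in flower were also among those that rose in bulbs, 158 of 307, and both named flower genes were present in some 222-day bulb libraries, at up to 18.7 and 9.98 FPKM. The 20 genes were chosen for their rise in bulbs and their overlap with the flower list was not counted, so these observations are not independent. The tables argue against bulb RNA mixed into the flower libraries: it would have to make up at least 54.3% of them, yet of 755 genes with at least 100 FPKM in each bulb library from 217 to 227 days, 7 lay under 0.5 times the level that share would bring in all 3 flower libraries, against 0 in bulbs at 202, 207 and 212 days. However, 738 of the 755 did reach the level, as did 8 of 9 genes that bulbs held at more than 10 times the mean of bud, leaf, pseudostem, sprout and root. Bulb libraries labelled as flower are argued against by 107 genes that were at least 4 times higher in every flower library than in all 24 bulb libraries, where no bulb group had more than 1. What stays open is a biological difference of the tissue itself. The sampled flowers may have held tissue that stores the same products as the bulb, which was not tested. Titles of the flower libraries begin with QSLJ and those of the bulb libraries with LJ. What these letters stand for was not examined, so the tissue sampled as flower rests on its label alone.

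More genes were called lower than higher in bulbs at 227 than at 192 days (28.3% higher). Lower depth at 227 days is argued against, since with every bulb library thinned to 12.8 M reads 28.3% were still higher, with 2541 higher and 6431 lower genes. A few genes taking a large share of the counts and a fall of most other genes cannot be told apart here. With libraries scaled without the 20 abundant genes, 60.8% of the called genes were higher and the median of all genes went from -0.28 to 0.18, but leaving out genes whose share rose to 34.4% moves all others up by construction. FPKM gives only shares, so whether absolute levels of most genes fell or rose stays open.

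Replicate 2 of the 227-day bulbs stood apart from its group. Lower depth is argued against, because its total was 27.0 M reads, above the 19.5 and 19.4 M of the others. A library of another group under a wrong label is argued against too: its highest correlation with the mean of any group was 0.876 (222-day bulbs), while in all groups other than 227-day bulbs every library correlated at 0.951 or more with its own. Plant material of another genotype is a candidate explanation, since 146 genes present in all 41 other libraries were near 0 here and 205 genes were seen here alone, against at most 0 and 2 for any other library. It was found and examined on the same data, and sequence variants, which could decide it, were not analysed here.

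Whether chance could give such counts was examined by regrouping the same libraries. For 3 results along age, only the real order or grouping, 1 of 100, gave as many genes. The real order gave 2921 genes rising and 5718 falling with age, against at most 2421 in the others. The real grouping gave 13088 genes differing among ages, against at most 2506. Libraries were shuffled singly, so this shows that they were not exchangeable between ages. Where replicates are not separate plants, it cannot exclude chance differences between the plants sampled at each age. For tissues, each random grouping was counted by its largest of the 7 tissue counts, and the highest of these was 1362. The real grouping alone, 1 of 100, reached the counts for bud (1903) and root (1797). Those for leaf (979), flower (361), sprout (279), bulb (260) and pseudostem (218) were reached by 3 of 100, a share under 0.05. Regrouping mixes unlike tissues and widens the spread within groups, so it tests whether the tissues differ at all and not a single tissue against the rest. A grouping with 1362 genes, several times the real counts of flower, sprout, bulb and pseudostem, points to a structure of these samples. Splits of 3 against 3 number 10 and are too few for a share under 0.05. At 227 against 192 days 2531 genes were higher and 6417 lower, against at most 6 in either direction in the other splits. The steps gave 294 against 2, 2126 against 0, 11 against 2, 697 against 1, 1145 against 0, 1190 against 262, and 1 against 290, where 7 of the 10 splits between 222 and 227 days called at least as many genes as the real one. A split with 290 calls points to a structure of these 6 libraries, and what made it was not tested. For the lists, the size of the median was 2.01 against at most 0.85 for bud, 1.27 against 0.56 for flower, 0.79 against 0.69 for pseudostem, 0.31 against 0.52 for root (4 of 10 as large), 0.21 against 0.31 for sprout (4 of 10), 0.16 against 0.17 for leaf (2 of 10) and 0.03 against 0.25 for bulb (9 of 10).

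Some bulb libraries correlated better with the mean of another age than with that of their own. Each library was left out of its own mean, which therefore rested on 2 libraries, against 3 for every other group. This favours other ages, and small gaps may come from it alone. Replicate 3 of the 207-day bulbs correlated best with the mean of 212-day bulbs (r = 0.976, against 0.957 with its own age), and replicate 1 of the 217-day bulbs with that of 202-day bulbs (0.975 against 0.969). Replicate 2 of the 222-day bulbs was nearest to 227-day bulbs (0.967 against 0.960). All 3 libraries of the 227-day bulbs were nearest to 222-day bulbs, replicates 1 and 3 at 0.981 and 0.978 against 0.947 and 0.952 with their own mean, which includes replicate 2. Replicate 3 of the 217-day bulbs held 19.2% of summed FPKM in the 20 abundant genes, against 5.34% and 5.39% in its group.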
